A study of Mus musculus with 2 samples.

How the data were processed

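Liver RNA was profiled on 2 Affymetrix whole-transcript mouse gene arrays, 1 for wild-type (WT) mice and 1 for E4bp4-LKO mice. Per the labels' protocols, male mice went onto a high-fat diet at 2 months of age and stayed on it for 12 weeks, under 12 hours of light and 12 hours of dark at 25 °C. Total RNA was extracted with TRIzol and chloroform. Biotinylated cDNA was prepared from 400 ng of it with the manufacturer's WT Plus kit, per the labels' protocols. The RNA of several mice was pooled before hybridisation, per the series description. The number of mice per pool and the hour of collection are not given in the sources used here.

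The deposited values are log2 intensities, 1 per probe set and array. RMA and R 3.4.0 are named in the submitters' processing notes. RMA is a method that corrects background, equalises the distributions of the arrays by quantiles and summarises probes into probe sets on the log2 scale. It compresses differences of dim genes towards 0. The scale was checked on the values: they ran from 1.25 to 12.78 on the WT array and from 1.18 to 12.82 on the E4bp4-LKO array, with medians of 3.74 and 3.75. No gene-wise centring was visible. Scanner files and per-probe detection calls were not used here, so background was judged from the level alone.

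The table held 41345 probe sets. The platform annotation gave 1 gene symbol to 23521 of them, several symbols to 1814 and none to 16010. Of the probe sets with 1 symbol, 23328 were matched through their Entrez identifier to the RefSeq gene table of assembly GRCm38.p6, and no symbol changed by this match. Probe sets with several symbols or none were left out of the gene comparisons. The probe sets of a gene were averaged, which gave 22180 genes, 21098 of them with a single probe set. A floor was set at the median of the genes' mean over both arrays (4.20 on the log2 scale), and 11090 genes lay above it.

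With 1 array of pooled RNA per genotype there are no replicates, so no standard error, p-value or test of genotype can be given. Each difference is the E4bp4-LKO value minus the WT value and describes these 2 arrays. The precision of an array comparison is limited by the number of arrays. As a measure of probe disagreement only, the 555 genes above the floor with 2 probe sets gave differences whose standard deviation between the probe sets of a gene was 0.22 on the log2 scale. The central 95% of the genes above the floor differed by between -0.54 and 0.49.

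Before the data were examined, 35 gene lists, the floor, the fold threshold of 1.5 and the rule for naming genes were fixed. Named are the targeted gene, the 12 genes with the largest difference in each direction above the floor (leaving out predicted or numbered gene models, small RNAs, receptor segments and olfactory or vomeronasal receptors), and up to 4 members of each list with the largest absolute difference, plus the best known members of a list. For each list, the median difference of its members above the floor was set among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart when its median lay below the 2.5th or above the 97.5th percentile. Genes of a list are not independent replicates, so this percentile describes the arrays and is no test of genotype. Lists with fewer than 5 members above the floor have values only. The lists cover the core clock, PAR bZIP factors and their reported liver targets, fatty acid synthesis, cholesterol synthesis, bile acids, fatty acid oxidation, lipid droplets, lipoproteins, the unfolded protein response, the integrated stress response, glucose handling, insulin and IGF signalling, AMPK, xenobiotic metabolism, NRF2 targets, interferon response, acute phase, cytokines, male-biased and female-biased liver genes, oxidative phosphorylation, cell cycle, immediate early genes, hepatocyte zonation, and markers of hepatocytes, cholangiocytes, endothelial cells, stellate cells, macrophages, T and NK cells, B cells, neutrophils, erythroid cells and adipocytes. Lists of skeletal muscle, squamous epithelium and Y-linked genes were added after the largest differences had been seen.

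The procedure was tested on simulated data made by shuffling the differences of the 11090 genes within expression bins, with fewer random lists per draw. Of 200 unshifted random lists of 18 genes, 5.0% were called apart. A share near this holds by construction, since the lists and their random lists came from the same shuffled values. Shuffling also unlinks genes that change together, so the simulation does not cover lists of such genes. Lists shifted by 1.1-fold were called in 67.0% of 200 draws, those shifted by 1.2-fold in 99.5% and those shifted by 1.3-fold in 100%. For single genes, known folds were added to shuffled differences trimmed to their central 95%. Of 50 genes changed by 1.5-fold, 36.0% passed the 1.5-fold threshold, against 92.0% of 50 genes changed by 2-fold. All of those changed by 3-fold or 4-fold passed, which the trimming fixed in advance. These shares rest on the spread between genes of this 1 pair of arrays, not on replicate noise, so they do not measure the power of the comparison.

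Alternatives tried were fold thresholds of 1.3 and 2, no floor, a floor at the 75th percentile (6.28), centring on the median gene, removal of the intensity trend by loess (span 0.3), the brightest probe set per gene, and random lists not matched on expression. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures matplotlib 3.10.9.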

Results

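E4BP4 (gene symbol Nfil3) is a transcription factor of the basic leucine zipper family that represses genes through the same DNA element that the PAR bZIP activators DBP, TEF and HLF use. The study asked how gene expression in the liver of mice on a high-fat diet differs between WT mice and mice of the E4bp4-LKO genotype, described as E4bp4-deficient. Each genotype was represented by 1 array hybridised with RNA pooled from several male mice fed the diet for 12 weeks. No difference below has a replicate error, and none has been tested against the variation between mice. The 2 arrays had nearly the same distribution of values, with medians of 3.74 (WT) and 3.75 (E4bp4-LKO) on the log2 scale. Across all 22180 genes their values correlated at r = 0.993; genes are not independent replicates.

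Nfil3, the targeted gene, was lower on the E4bp4-LKO array, at 4.47 against 5.94 on the WT array. This log2 difference of -1.47 is 2.77-fold and places Nfil3 among the 12 genes that were lowest relative to WT. The E4bp4-LKO value lay just above the floor of 4.20. The positions of its probes relative to the deleted part of the gene were not used here, so the remaining signal cannot be read as remaining transcript.

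Among the 11090 genes above the floor, 167 were at least 1.5-fold higher and 229 at least 1.5-fold lower on the E4bp4-LKO array, 3.57% of the genes together. At 2-fold the numbers were 43 and 45. The largest difference was that of Hsd3b5, a steroid-reducing enzyme of male mouse liver, at 8.45 against 3.92, a log2 difference of 4.53. Its WT value lay below the floor. The keratins Krt4 and Krt13 followed, with differences of 2.95 and 2.26, and Krtdap, a keratinocyte protein, differed by 1.76. All 3 lay below the floor on the WT array. Slco1a1, an organic anion uptake transporter, was higher by 2.14 on the log2 scale, Serpina1e, an alpha-1-antitrypsin isoform, by 1.88, and the cytochrome P450 genes Cyp2c54 and Cyp4a12b by 1.78 and 1.42. The complement gene C4a, the serpin Serpinb1a, the acetyltransferase-like gene Nat8 and the ubiquitin-like gene Ubd were higher by between 1.41 and 1.66. Of these, C4a, Serpinb1a and Ubd lay below the floor on the WT array, so the size of their differences, like that of Hsd3b5 and the keratinocyte genes, is uncertain.

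In the other direction, Cyp2b13 had the largest difference, at 4.52 on the E4bp4-LKO array against 7.51 on the WT array (-2.99). The lipid droplet protein genes Cidea (-2.35) and Cidec (-1.57) were next to Sprr1a, a small proline-rich protein gene (-2.22), and Ly6d (-1.91) in this group. Gpnmb, a glycoprotein of lipid-laden macrophages, and Mmp12, the macrophage elastase, differed by -1.98 and -1.63. The E4bp4-LKO value of Gpnmb (4.06) lay below the floor, so the size of its difference is uncertain. Myh2 and Atp2a1, which encode a myosin heavy chain and the calcium pump of skeletal muscle, differed by -1.83 and -1.47. Gprc5b (-1.56) and Themis (-1.47) completed the 12 together with Nfil3. Probe sequences were not examined, so values of near-identical paralogs (Cyp2b9 and Cyp2b13, Cyp2a4 and Cyp2a5, Cyp4a12a and Cyp4a12b, and the Serpina1, Mup, Saa, Cyp2c and Cyp3a families) may share signal and are uncertain one by one. Such paralogs did not all move alike. Serpina1a (-0.005), Serpina1c (0.06) and Cyp4a12a (0.15) differed little beside Serpina1e and Cyp4a12b, while Cyp2b9 (-1.02) was lower with Cyp2b13.

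**Figure D1:**
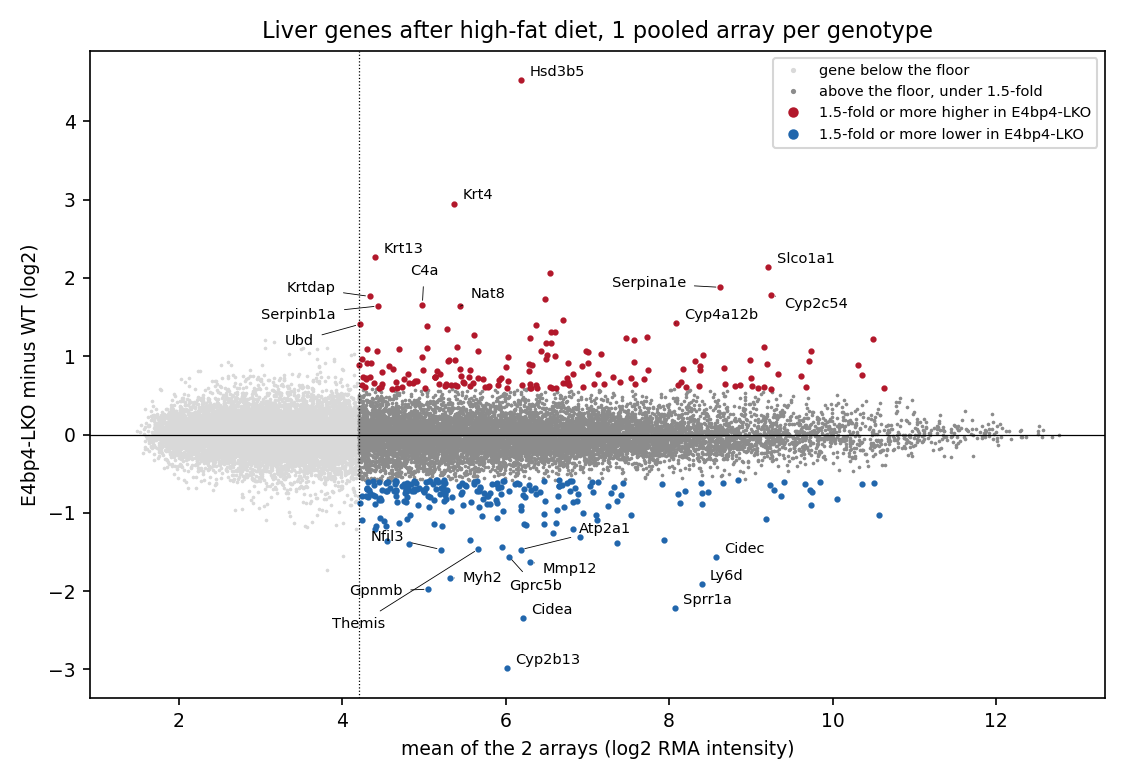
Each point is 1 of 22180 genes, with the mean of the 2 arrays on the x axis (log2 RMA intensity) and the E4bp4-LKO minus WT difference on the y axis (log2). The dotted line is the floor of 4.20; red and blue points are the 167 and 229 genes that differ by 1.5-fold or more, and labels mark the targeted gene and the 12 named genes in each direction.

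Of the 32 lists with enough members, 9 stood apart from matched random lists, 2 of them higher and 7 lower on the E4bp4-LKO array. For 32 unrelated random lists, 1.6 would be outside the central 95% by construction. Genes with male-biased expression in mouse liver were higher as a group. Their median difference was 0.43 (1.35-fold, 16 members, SD between members 1.19), above all 10000 random lists. At least 1.5-fold higher were 7 of the 16 and none was lower by as much. Besides Hsd3b5, Slco1a1 and Cyp4a12b these were Susd4 (1.31), the fatty acid elongase Elovl3 (1.21), Serpina4-ps1 (1.07) and the urinary protein gene Mup21 (0.72). The abundant Mup3 and Mup20 differed by 0.11 and 0.08, and Cyp2d9 by -0.07.

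The 13 female-biased genes did not stand apart as a list (median -0.04, percentile 37.4), and their members differed in both directions. Cyp2b13, Cyp2a4 (-1.38), Cyp2b9 (-1.02) and the peroxisomal transporter gene Abcd2 (-0.87) were at least 1.5-fold lower. Cyp3a44 was higher, by 1.27. The labels give male mice for both pools. Xist, the RNA that coats the inactive X chromosome in females, was below the floor on both arrays, at 2.81 (WT) and 2.99 (E4bp4-LKO).

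Genes of lipid droplets and lipid uptake were lower on the E4bp4-LKO array. Of 21 members, 20 had a negative difference, 7 were at least 1.5-fold lower and none higher by as much. The median difference was -0.30 (1.23-fold lower, SD between members 0.56), below all 10000 random lists. The 7 were Cidea, Cidec, the droplet coat gene Plin4 (-0.80), the lipoprotein receptor gene Vldlr (-0.72), the monoacylglycerol acyltransferase gene Mogat1 (-0.68), Pparg, the nuclear receptor that drives fat storage genes (-0.67), and the lipase gene Lpl (-0.59). The fatty acid transporter Cd36 and the abundant droplet protein gene Plin2 differed by -0.30 and -0.19. The adipocyte marker list, which shares Cidec, Plin4, Fabp4 and Lpl with this list, had a median of -0.24 (percentile 0.42, 8 members), but its percentile was 16.6 when members below the floor were included. Adipoq, Lep and Plin1, markers of adipose tissue itself, lay below the floor on both arrays. Without the 4 shared genes, an alternative chosen after seeing the data, the lipid droplet list still had a median of -0.30, below all random lists.

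Fatty acid oxidation and ketogenesis genes were lower by a smaller amount, with a median of -0.17 (1.12-fold, 21 members, SD 0.24, percentile 0.035). A negative difference was seen for 18 of the 21, but only Vnn1, a pantetheinase gene and PPARα target, was lower by 1.5-fold or more (-0.78). Acot2 (-0.46), Bdh1 (-0.41) and Pdk4 (-0.40) followed. Cpt1a, the gate of mitochondrial fatty acid import, differed by -0.22 and Ppara by -0.17. Fatty acid synthesis genes did not stand apart (median 0.04, percentile 84.7), and none of their 18 members differed by 1.5-fold; the largest differences were Thrsp (0.30), Gpam (-0.26), Acss2 (0.21) and Me1 (-0.20). The same held for the 17 cholesterol synthesis genes (median -0.05, percentile 27.1), of which Tm7sf2 differed most (0.37), followed by Lss (-0.22), Hmgcs1 (-0.20) and Msmo1 (0.19). In the apolipoprotein list (median 0.08, percentile 95.2), Angptl8, an insulin-responsive inhibitor of lipoprotein lipase activity, was higher by 0.91, while Apoe (-0.30), Apoa5 (0.23) and Apoc1 (0.18) differed less.

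Hepatic stellate cell and fibrosis genes were lower on the E4bp4-LKO array, all 20 members above the floor having a negative difference. Their median was -0.40 (1.32-fold, SD between members 0.29), below all 10000 random lists. The fibrillar collagen genes Col3a1 (-1.15) and Col1a1 (-1.01) and the proteoglycan gene Lum (-0.69) were at least 1.5-fold lower. Des (-0.58) and Col1a2 (-0.58) were just under that threshold (Col1a2 lay below the floor on the E4bp4-LKO array), and Lrat, the retinyl ester enzyme of quiescent stellate cells, differed by -0.56. Acta2, the actin of activated stellate cells, differed by -0.39. Skeletal muscle genes were also lower on this array: 18 of 20 genes of a list written after Myh2 and Atp2a1 had been seen, with a median of -0.33, including Acta1 (-0.91) and Tnnt3 (-0.86). Des is also expressed in muscle. The fibrosis list was not run with allowance for other tissue in the WT pool. What part such tissue had in the list's difference is therefore unknown, for the collagen genes as for Des.

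Kupffer cell and macrophage markers did not stand apart as a list (median -0.07, percentile 19.8, 21 members). Within it Gpnmb and Trem2 (-0.67), genes of lipid-associated macrophages, were at least 1.5-fold lower, and Lgals3 (-0.57) and Itgax (-0.54) were nearest to them. Gpnmb and Itgax lay below the floor on the E4bp4-LKO array. Clec4f and Timd4, markers of resident Kupffer cells, differed by 0.17 and 0.35. The cytokine and chemokine list also did not stand apart (median -0.10, percentile 14.8). Ly6d was its only member below the 1.5-fold threshold; Vcam1 differed by -0.56 and Ccl2 by 0.53. In the acute phase list (median 0.05, percentile 89.8) the serum amyloid genes Saa3 (0.89) and Saa2 (0.83) were higher and the metallothionein gene Mt2 lower (-0.73), with Orm3 at -0.50. Interferon response genes had a median of -0.06 (percentile 23.5); Usp18 was lower by 1.52-fold, Ifit1 differed by -0.41, Zbp1 by 0.32 and Rsad2 by -0.29.

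Cell cycle genes were lower on the E4bp4-LKO array. All 17 members above the floor had a negative difference, 8 were at least 1.5-fold lower, and the median of -0.53 (1.44-fold, SD between members 0.29) lay below all 10000 random lists. The replication licensing genes Mcm5 (-0.93), Mcm6 (-0.78), Mcm2 (-0.78) and Mcm3 (-0.77), the mitotic kinase gene Aurka (-0.85), the G1 cyclin gene Ccnd1 (-0.85), the proliferation marker Mki67 (-0.75) and Cdc20 (-0.71) were the 8. Pcna, which also serves DNA repair, differed by -0.14. Of the 8, Mcm5, Cdc20 and Aurka lay at 4.59, 4.42 and 4.32 on the E4bp4-LKO array, close to the floor. Ccne1, another member, lay below it on that array (4.18).

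**Figure D2:**
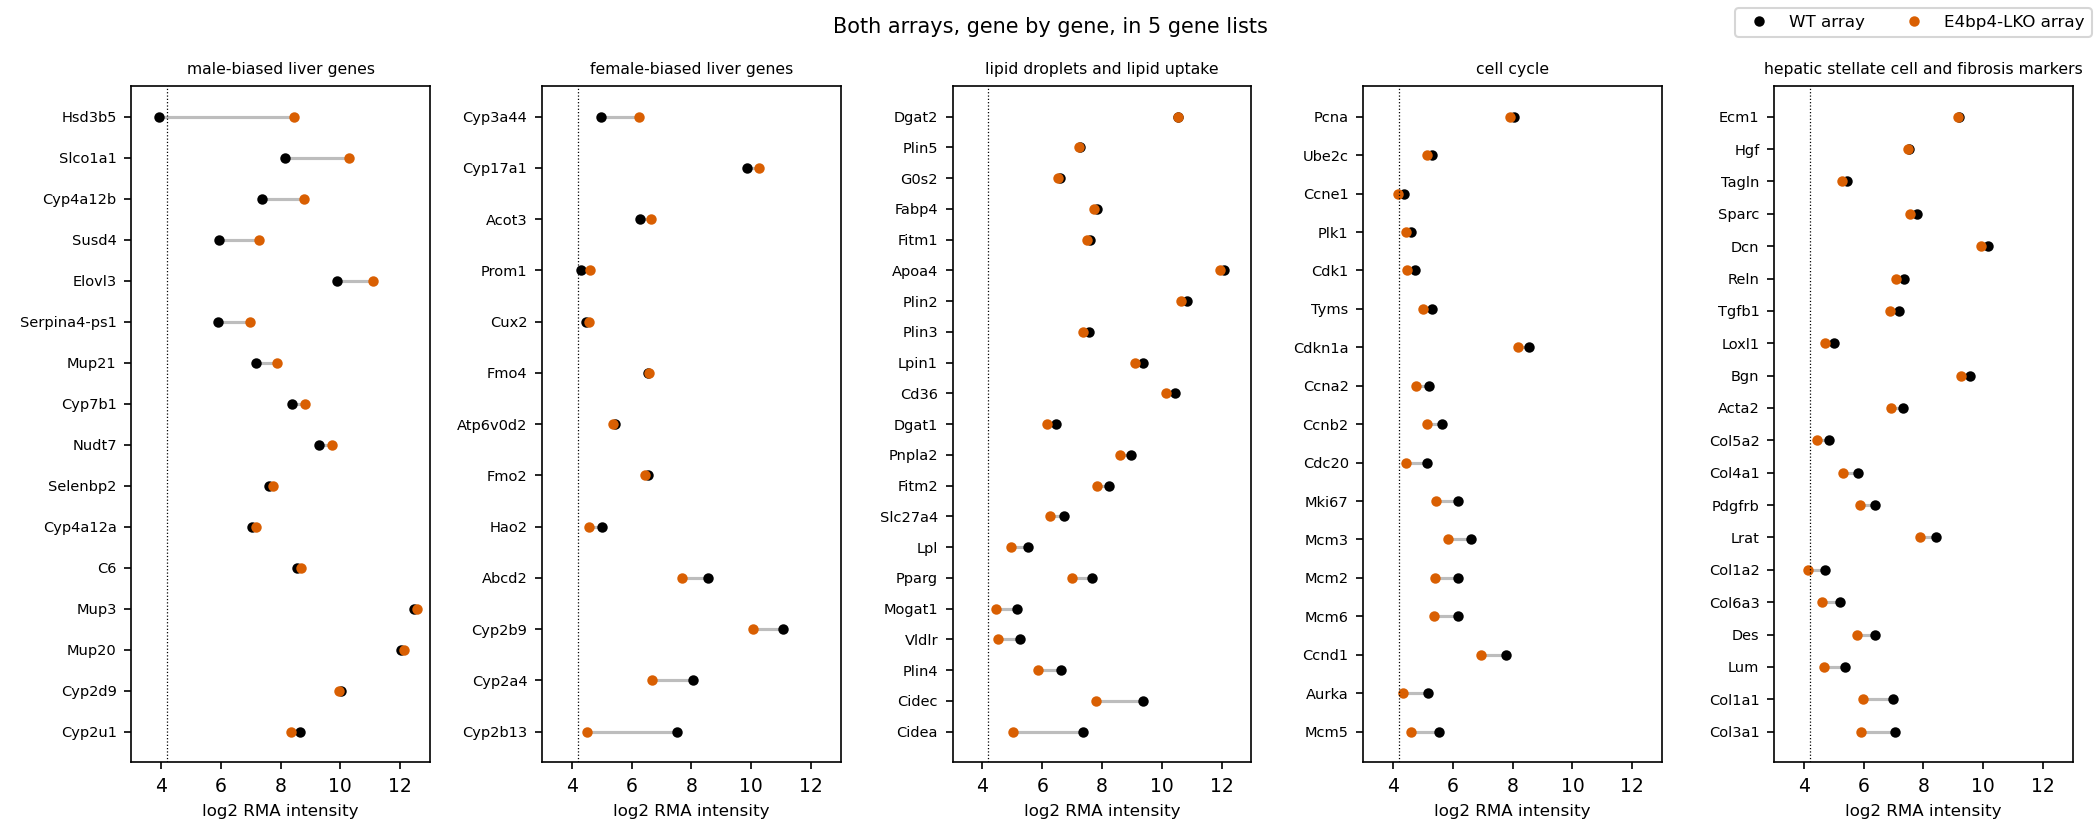
Each row is a gene of 1 of 5 lists, with its value on the WT array (black) and on the E4bp4-LKO array (orange) in log2 RMA intensity on the x axis; the dotted line is the floor of 4.20. Male-biased genes such as Hsd3b5 and Slco1a1 lie to the right on the E4bp4-LKO array, while all 17 cell cycle genes, all 20 stellate cell and fibrosis genes and 20 of 21 lipid droplet genes lie to the left.

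The core clock list did not stand apart (median 0.00, percentile 65.7, 12 members), because its members differed in opposite directions. A median of signed differences cannot show a change of that kind. At least 1.5-fold higher were 2 of the 12 members and at least 1.5-fold lower 3, against 3.57% of all genes above the floor in either direction. Arntl, the positive factor BMAL1, was higher by 0.90 and Npas2, a paralog of Clock and partner of BMAL1, by 0.60. Per3 (-0.68), Nr1d1, the repressor REV-ERBα (-0.65), and Ciart (-0.63) were at least 1.5-fold lower. Cry1 differed by 0.32, Clock by -0.05 and Per1 by -0.03. The hour at which either pool was collected is not given in the labels.

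PAR bZIP factors and their reported liver targets had a median of -0.23 (1.18-fold lower, 12 members, SD 0.58, percentile 0.04). Loss of a repressor that acts through the same DNA element would by itself give higher targets, so this direction is the opposite. Since the hour of collection is not given, a difference in hour between the pools cannot be told apart from the genotype here either. Dbp itself (-1.08) and the cytochrome P450 genes Cyp2a4 and Cyp2a5 (-1.04) were at least 1.5-fold lower, while Tef and Hlf differed by -0.22 and -0.03. Fgf21, a fasting-responsive hormone gene, differed by -0.36. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.55. With a floor at the 75th percentile of expression the list no longer stood apart (percentile 40.8, 9 members). Cyp2a4 is also on the female-biased list; without it, an alternative chosen after seeing the data, the percentile was 0.1.

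Bile acid genes had a median only 0.07 above 0 (22 members, SD 0.60, percentile 97.9), and the list did not stand apart once the intensity trend was removed (97.1) or the random lists were left unmatched (96.7). Of its members, 14 were above 0 and 8 below, and a median of signed differences does not show such opposite changes. Slco1a1 was the only member at least 1.5-fold higher. The synthesis genes Cyp7a1 (0.55), Cyp7b1 (0.44), Cyp39a1 (0.43) and Akr1d1 (0.37) were higher by less than that. The uptake transporter gene Slco1a4 (-1.03) and the efflux pump genes Abcc3 (-0.71) and Abcc4 (-0.61) were at least 1.5-fold lower. NRF2 targets, which serve antioxidant defence, were lower with a median of -0.16 (1.12-fold, 15 members, SD 0.28, percentile 0.26). A negative difference was seen for 14 of the 15, and the glutathione transferase gene Gstm3 (-0.90) and Ugdh (-0.63) passed 1.5-fold; Gstm1 (-0.57) and Srxn1 (-0.36) followed. Xenobiotic metabolism genes did not stand apart (median -0.05, percentile 20.7): besides Cyp2b13 and Cyp2b9, Cyp2c55 was lower (-0.60) and the sulfotransferase gene Sult1d1 higher (0.77).

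Genes of glucose handling had a median of 0.02 (percentile 71.5) and none of their 16 members reached 1.5-fold. Ppp1r3b and Ppp1r3c, which direct phosphatase to glycogen, differed by 0.58 and 0.55, G6pc by 0.42 and Pfkl by -0.37. In the insulin and IGF list (median -0.04, percentile 38.2) Igfbp2 was higher by 0.94 and the insulin receptor substrate gene Irs2 lower (-0.72), with Grb10 at -0.40 and Sik1 at 0.39. AMPK subunits and upstream kinases differed by between -0.13 and 0.02 (median -0.05, percentile 36.6), with Prkag1 at -0.13, Prkab2 at -0.11, Stk11 at -0.09 and Prkag2 at -0.05. The 22 genes of the unfolded protein response had no member past 1.5-fold (median -0.03, percentile 37.2); Eif2ak3, which encodes the stress sensor PERK, differed most (-0.35), then Sdf2l1 (0.21), Derl3 (-0.20) and Xbp1 (0.19). In the integrated stress response list (median -0.00221, percentile 63.7) Ddit4 was higher by 0.87, and Nupr1 (-0.46) and Phgdh (-0.36) differed less.

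Oxidative phosphorylation genes (median 0.07, percentile 97.2, 21 members) lay just inside the random range, with Ndufa4 and Cox7a2 at 0.32 each, Ndufb8 at 0.28 and Ndufb5 at 0.22. Periportal hepatocyte markers were close to its edge too (median 0.10, percentile 96.9), with the urea cycle genes Ass1 at 0.65 and Cps1 at 0.30 and with Hsd17b6 (-0.71) and Hsd17b13 (-0.28) opposite. Ass1, the only periportal marker at least 1.5-fold higher, was dim, at 4.95 (WT) and 5.59 (E4bp4-LKO). Cps1 lay at 11.47 and 11.78. Pericentral markers had a median of -0.05 (percentile 20.9) and differed by less than 1.5-fold; Cyp2c38 (-0.39), Cyp1a2 (-0.27), Rhbg (-0.20) and Tbx3 (-0.19) were farthest from 0. General hepatocyte markers had a median of 0.07 (percentile 93.9), with the factor Foxa3 at 0.63 and the asialoglycoprotein receptor genes Asgr2 and Asgr1 at 0.17 and 0.14. Immediate early genes did not stand apart (median -0.05, percentile 33.1); Nr4a1 (1.40) and Klf4 (0.74, from a WT value below the floor) were higher, Gadd45b was lower (-0.83) and Klf6 differed by -0.47.

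Endothelial markers had a median of -0.09 (percentile 8.22) with no member past 1.5-fold; Lyve1 (-0.52), Vwf (-0.37), Oit3 (-0.32) and Cdh5 (-0.31) were farthest from 0. T and NK cell markers had a median of 0.07 (percentile 83.8, 8 members), with Cd4 at 0.66, Nkg7 at 0.42, Thy1 at 0.27 and Cd3e at 0.10. B cell and plasma cell markers had a median of -0.17 (percentile 5.5, 6 members), with Jchain at 0.63 and the class II genes H2-Eb1 at -0.32 and H2-Aa at -0.26, and Cd79a at -0.18. Cholangiocyte markers (4 above the floor), neutrophil markers (3) and erythroid markers (2) were too few for a percentile. Onecut1 was higher by 1.05, Epcam differed by 0.31, Csf3r by -0.21, Mmp9 by -0.20 and Klf1 by -0.11. Of the erythroid list, 10 genes were not analysed here.

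**Figure D3:**
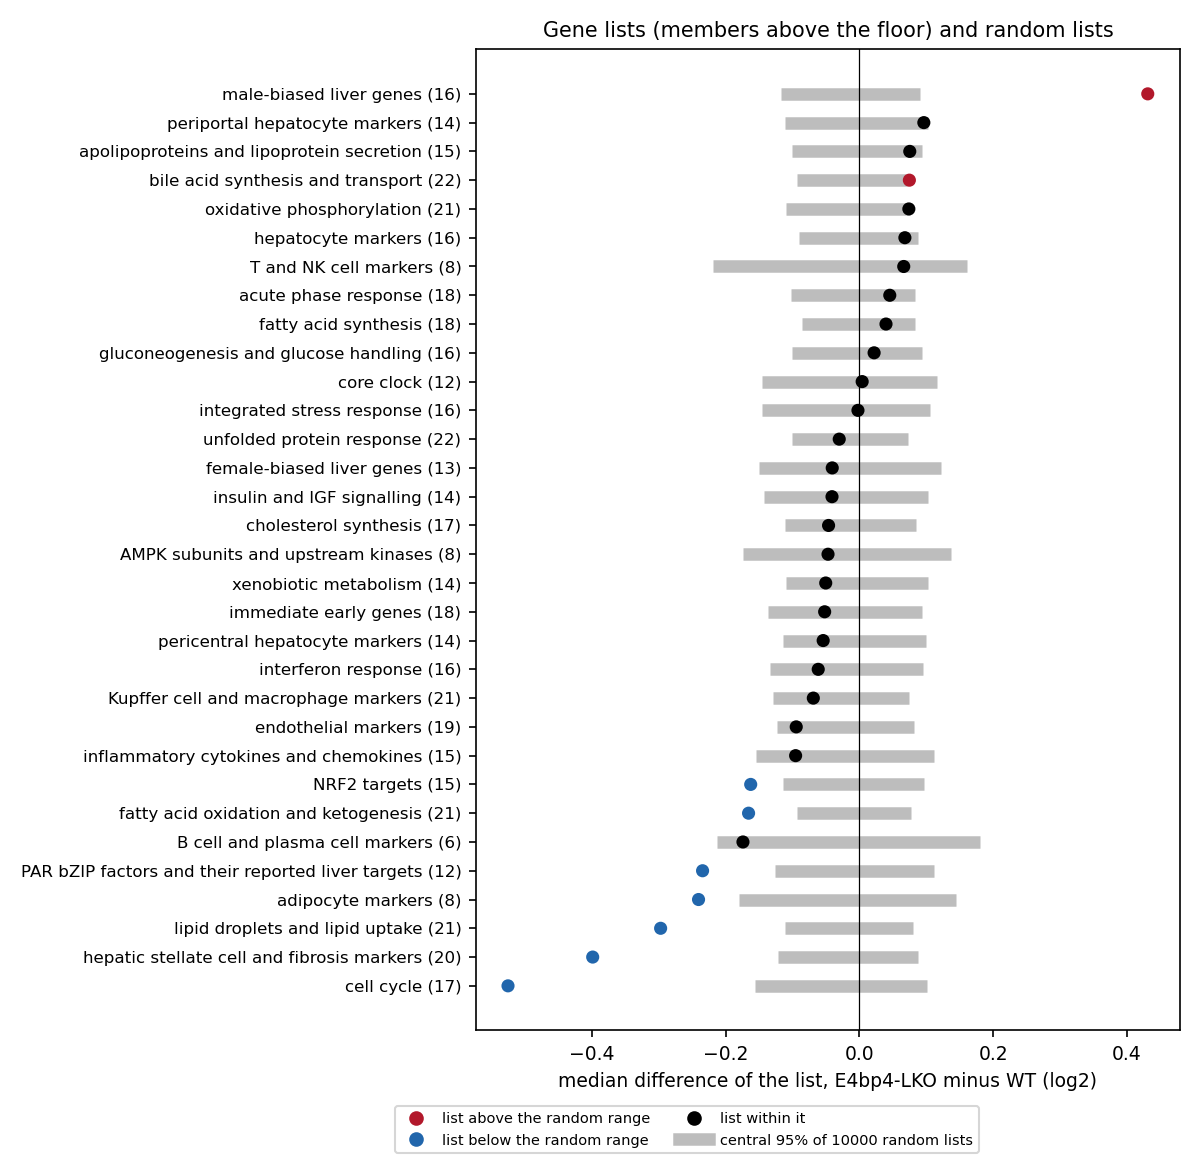
Each point is the median E4bp4-LKO minus WT difference (log2, x axis) of 1 of 32 gene lists, with the number of members above the floor in brackets; the grey bar is the central 95% of the medians of 10000 random lists matched on mean expression. The male-biased list (0.43) lies to the right of its bar, and the cell cycle (-0.53), fibrosis (-0.40) and lipid droplet (-0.30) lists lie farthest to the left.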

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

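The tests on the Nfil3 locus by probe numbering, on genes of like intensity, on an intensity-dependent bias, on the neighbours above the floor alone and on the individual animals pooled were chosen after the results had been seen. The other tests were written down before their values were computed, though after the largest differences had been listed.

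Probe sets without a single gene name enter none of the comparisons above. Of the 5487 such probe sets above the floor, 113 were at least 2-fold higher on the E4bp4-LKO array than on the WT array, and 66 were at least 2-fold lower. Among the 11090 named genes above the floor these numbers were 43 and 45, a smaller share in both directions. Whether probe sets without a single gene name are noisier was not tested, so their larger share cannot be read as an effect of the genotype. The largest difference among them was that of probe set 17209863, at 6.04 against 2.40. The next was probe set 17292632, at 6.42 on the E4bp4-LKO array against 3.03 on the WT array, a log2 difference of 3.39. The WT values of both lay below the floor of 4.20, so the sizes of these differences are uncertain.

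The number of probe set 17292632 lies between those of Auh and Nfil3, and it is the only one between them. Auh, an RNA-binding enzyme of leucine breakdown, is the nearest measured protein-coding neighbour of Nfil3 on 1 side and was higher on the E4bp4-LKO array (7.13 against 5.97, a difference of 1.16), while Nfil3 was lower. The other 19 neighbours of Nfil3 had a median absolute difference of 0.14 (percentile 46.8 of random lists of like mean), and the 9 of them above the floor had one of 0.12 (percentile 38.7), which argues against a shift of the region as a whole, although 10 of the 19 lay below the floor and 2 of the 19 differed by 1.5-fold or more, Cks2 (0.77) and Sema4d (-0.62, mean below the floor). A single extreme gene stays open, because Auh was picked for its size and place, so that the 0.66% of genes of like mean that differ by as much (16 of 2418) decides nothing. A candidate explanation is that transcription from the disrupted Nfil3 gene runs on into the sequence next to it and into Auh; the direction of the 3.39 goes with that, but the position and strand of the probe set were not read from a genome, and a direct effect of E4BP4 on Auh was not tested and stays open.

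Genes of other tissues separated the arrays in both directions. On the WT array, the skeletal muscle genes Myh2, Atp2a1, Myh4 (-1.40 as E4bp4-LKO minus WT), Myh1 (-1.16) and Ckmt2 (-1.09) were higher (the last 3 below the floor on the E4bp4-LKO array), and the 20 further muscle genes (13 of them above the floor, with Acta1 at 7.71 on that array and 6.80 on the other) had a median of -0.33, at percentile 0 of matched random lists, which is consistent with a trace of muscle in the WT pool. Neb (0.22) and Casq1 (0.01) did not share the direction, and Mylpf (-0.19), Tnni2 (-0.18) and Tcap (-0.26) shared it with small differences. On the E4bp4-LKO array, Krt4, Krt13, Krtdap and Cnfn (1.38) were higher, and 22 further genes of squamous epithelium had a median of 0.21, at percentile 100, which is consistent with a trace of such epithelium in that pool, although 18 of the 22 lay below the floor, Krt14 (0.19) and Krt6a (0.28) among them, and Krt78, 1 of the 4 above it, went the other way (-0.45). A change of these genes within liver cells was not tested; Sprr1a and Ly6d, also expressed in such epithelium, went the other way.

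Male-biased liver genes were higher on the E4bp4-LKO array as a list. Female animals in the WT pool would bring Xist, which differed by 0.18 (E4bp4-LKO minus WT) and was below the floor on both arrays, so this explanation is argued against; the Y-linked genes Eif2s3y, Kdm5d and Uty were higher on the E4bp4-LKO array by 0.51, 0.49 and 0.04, a direction that such animals would also give. An intensity-dependent bias would shift genes of like mean alike. The medians of random lists of like mean reached 0.0904 at the upper end of their central 95%, and the list's median was 0.43. These are the same random lists by which the list was called apart. They show that genes of like mean did not share its shift, but are no separate test of such a bias. With 1 array per genotype, a difference between the individual animals pooled cannot be told apart from an effect of the genotype. That holds for the list, of which 14 of 16 members were above 0, as it does for single genes such as Hsd3b5 or Slco1a1. The genotype stays open as the biological explanation, untested.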

How the results depend on the processing

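The counts without muscle and squamous epithelium genes, and the lists without members shared with another list, were chosen after the results had been seen. No paired analysis was possible because each genotype has 1 array, and for the same reason no array could be left out. The counts of genes depended on the threshold and the floor: at 2-fold 43 genes were higher and 45 lower, at 1.3-fold 572 and 685, without a floor 295 and 365, and with a floor at the 75th percentile 84 and 72, so that the larger side changed. Centring (186 higher and 205 lower), removal of the intensity trend (187 and 203) and the brightest probe set (165 and 237) moved neither count by more than 1.5 times. Nor did leaving out the muscle and squamous epithelium genes (160 and 220). Against 167 and 229 as deposited, centring and trend removal brought the sides closer together, so the excess of lower genes depends in part on centring. The lists of male-biased genes (percentile 100 also without the bile acid genes), lipid droplets, fatty acid oxidation, NRF2 targets, cell cycle and fibrosis stood apart under all alternatives run for them. The list of PAR bZIP factors and targets did not with a floor at the 75th percentile (percentile 40.8), where 9 of its 12 members remained. The adipocyte list did not without a floor (16.6), and without the genes shared with the lipid droplet list too few members were left for a percentile. The bile acid list did not once the intensity trend was removed (97.1) or the random lists were unmatched (96.7). Oxidative phosphorylation did stand apart after removal of the trend (97.6) and with the brightest probe set (98.8), as did periportal markers with the brightest probe set (99). The cause was not tested. The other 21 lists stayed inside the random range under the alternatives run for them. With the floor at the 75th percentile too few members were left for the cell cycle, adipocyte, integrated stress response, cytokine, T and NK cell and B cell lists. Of the 145 genes named by the size of their difference, centring or trend removal moved none by more than 0.03, and none changed direction with these or with the brightest probe set. Other members named in the text were not run, and the differences of Per1 and Hlf (-0.03 each) are as small as that shift. Median and mean had opposite signs for the core clock (0.00407 and -0.00296), the integrated stress response (-0.00221 and 0.00112) and insulin and IGF signalling (-0.0411 and 0.0213), none of which stood apart; for the integrated stress response the percentile (63.7) also lay on the other side of 50 from its median. The floor is the median of all genes by definition and no detection call was used, so how far a dim gene lay above background is unknown.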

Other observations

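The groups in this part were picked after their values were seen, so their percentiles describe them and are no independent evidence. The 6 terminal complement genes examined (C6, C7, C8a, C8b, C8g and C9), all above the floor, were higher on the E4bp4-LKO array. Their median was 0.32 (percentile 100 of matched random lists after rounding), and C8b differed most, at 10.18 against 9.25. Other genes of that pathway were not examined as part of this group. The 12 carboxylesterase genes had a median of 0.17 (percentile 99.7), and 8 of them were above 0, with Ces3b at 0.62 and Ces1d at 0.61, while 4 were below 0, with Ces2e at -0.27 and Ces2g at -0.25. The replication licensing complex was lower, since all 6 of Mcm2 to Mcm7 had a negative difference (median -0.78), with Mcm4 at -0.97 and Mcm7 at -0.44. All 11 genes of collagens I, III, IV, V and VI above the floor had a negative difference as well (median -0.49), from -0.10 for Col5a1 to -1.15 for Col3a1. The 6 mu class glutathione transferase genes had a median of -0.27 (percentile 0.24), with Gstm3 at -0.90 and Gstm7 at 0.31.

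Transporters of organic ions differed in both directions, and neither family stood apart as a whole. In the Slc22 family (13 genes, median -0.03, percentile 48.9), Slc22a26 (5.58 against 4.48) and Slc22a7 (a difference of 1.03) were higher and Slc22a27 was lower (-1.26). In the Slc17 family (7 genes, median 0.04, percentile 75.6), Slc17a1 (a difference of 1.24) and Slc17a8 (8.18 against 6.97) were higher. Other single genes with large differences were Bcl6, a repressor with higher expression in male liver (-1.20, opposite to the male-biased list), the receptor genes Egfr (1.11) and Avpr1a (1.24), and Noct, a rhythmic gene (1.31). Bhlhe41, a clock repressor on the core clock list, lay at 3.23 on the E4bp4-LKO array and 4.79 on the WT array. Its mean was below the floor, so it did not enter that list's median.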
